A study of Strigamia maritima with 9 samples.

How the data were processed

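DNA affinity purification sequencing (DAP-seq) measures where a protein made outside the cell binds to naked genomic DNA. Per the labels' protocols, adult *Strigamia maritima* DNA (a centipede, of the strain used for the genome sequence) was sonicated to a mean length of 200 bp, ligated to sequencing adapters and offered to a HaloTag fusion of a CopiaMBD domain, a methyl-CpG binding domain carried by a Copia retrotransposon. The HaloTag is a protein tag that attaches covalently to its ligand on beads, and the bound DNA was amplified for 20 PCR cycles. For the amplified-DNA libraries (ampDAP-seq) the same kind of DNA first went through 11 PCR cycles, which copy the sequence and not the methyl groups. By design, native-DNA libraries therefore keep methylated cytosines and amplified-DNA libraries lose them. The methylation of neither was measured here.

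The labels name 9 samples. There was 1 library for each of the 3 domains on native DNA, 1 for each on amplified DNA, 1 with the HaloTag alone on each kind of DNA, and 1 MethylC-seq sample (bisulfite sequencing after 6 PCR cycles), which is not analysed here. Groups were taken from the sample titles. Every group held 1 library, so no group has replicates. The only p-value across samples comes from an exact sign-flip permutation test of the log2 ratio of native to amplified peak numbers over the 3 domains, added after the data were seen.

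Per the file headers, peaks were called per library by the authors with MACS2 version 2.1.0.20150731 at a q-value of 0.05, each domain against the HaloTag-only library of the same DNA kind. The larger library was sampled down to the smaller, 1 tag was kept per position, the effective genome size was set to 173.6 Mb, and local control levels were taken over 1 and 10 kb. The submitters' processing notes also name CASAVA 1.8.2, fastp, Bowtie, Bowtie2 and BS-Seeker2, without saying which step each served. The genome build is not given in the sources used here, and positions are given as the files give them, 1-based, on scaffolds with JH names and on contigs with AFFK names.

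The deposited pileup is a coverage signal, the number of fragments over the summit after down-sampling, and was not scaled to a fixed depth. The deposited fold enrichment is the authors' ratio of that pileup to the local control level. The deposited −log10 p and −log10 q values are those of the peak caller for each summit. Fold enrichment and q-value, the authors' values throughout, were used to describe, rank and filter peaks within lists, to compare native peaks with and without an amplified-DNA peak, and to recover control levels. Fold enrichments of different lists were correlated at overlapping peaks, and their sizes were not tested between lists.

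Depth was read from the headers. Tags at unique positions numbered 2239324, 2224965 and 2044955 for CopiaMBD1, CopiaMBD2 and CopiaMBD3 on native DNA against a control of 4050757, and 3772201, 3698032 and 3488873 on amplified DNA against a control of 3685424. After down-sampling, the amplified-DNA calls used 1.65, 1.66 and 1.71 times as many tags as the native-DNA calls. Tags at repeated positions made up a fraction of 0.04 to 0.08 of the domain libraries. PCR reads without molecular identifiers are not independent molecules, so the intervals given below cover counting error only.

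Peak lists were compared by overlap of at least 1 bp with Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and bedtools 2.31.1, and plots were drawn with matplotlib 3.10.9. Shares of peaks carry exact Clopper-Pearson 95% intervals. Each overlap was set against 1000 random placements of the same peaks, a permutation test of peak positions (bedtools shuffle), on the 6071 sequences that hold a peak in any list, each taken from its start to the end of its last peak, 125.1 Mb in all. The smallest one-sided p these placements can give is 0.001. This p describes the placement of peaks in these libraries, not a spread between samples. On simulated lists of 7461 peaks with 0, 20 and 60% of peaks planted on a CopiaMBD3 peak, the method returned 5.21, 24.1 and 62.3%, with random values of 5.12 to 5.22%.

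Because the 3 domains share a HaloTag-only library within each DNA kind, libraries without binding were simulated against a single control (20 simulations, with uniform coverage and with coverage varying per kb by a gamma factor of shape 4), and the share of chance calls in common was counted. Fold enrichments at overlapping native peaks were compared by Pearson's r on the log2 scale and Spearman's rho, with 95% intervals from 1000 bootstraps over sequences. Native peaks with and without an amplified-DNA peak were compared by a two-sided permutation test of the median with 100000 permutations of peak labels, adjusted by Benjamini-Hochberg over the 3 domains. The local control level at each summit was recovered from pileup and fold enrichment as (pileup + 1) / fold − 1.

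The plan did not name the simulation of libraries without binding, which calls at the weakest p of each list, or the Benjamini-Hochberg adjustment. The other comparisons, apart from the sign-flip test, and the alternatives were fixed before the data were examined. So was the rule for naming peaks. The rule takes the 3 peaks of highest fold enrichment in each list, and the 5 amplified-DNA regions called for all 3 domains with the highest lowest fold. Alternatives were a −log10 q of at least 10, a fold of at least 5, merging of peaks within 500 bp, sequences spanning at least 100 kb, an overlap of 50% of the shorter peak or a gap of up to 500 bp, circular shifting of each sequence's peaks as the random placement, and equal numbers of peaks per list. Comparisons restricted to scaffolds without the AFFK contigs, to peaks with a control level under 3 times the lowest of the list, and to peaks at the lowest control level (within 2%) were added after the data were seen. CpG density, bases flanking CpG, position relative to genes, gene groups and repeats need a genome of the matching build, which was not used here, so these planned comparisons were not run and no gene is named.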

Results

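The series asks where 3 methyl-CpG binding domains, carried by a family of Copia retrotransposons in the centipede *Strigamia maritima*, bind the animal's own DNA, and whether that binding needs the methylation the DNA carries. Binding was mapped for CopiaMBD1, CopiaMBD2 and CopiaMBD3 on native genomic DNA and on DNA amplified to remove its methylation. There was 1 library per domain and DNA kind, and a HaloTag-only control for each DNA kind. The 6 peak lists held 37176 native-DNA and 660 amplified-DNA peaks. Native-DNA calls rested on 2044955 to 2239324 tags and amplified-DNA calls on 3488873 to 3685424. No group had a replicate, so every comparison describes these libraries.

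On DNA amplified to remove its methylation, nearly all called binding sites of the 3 domains were missing. CopiaMBD1 had 7461 peaks on native DNA and 358 on amplified DNA, CopiaMBD2 had 14001 and 133, and CopiaMBD3 had 15714 and 169. Native DNA thus gave 20.8 times as many peaks for CopiaMBD1, 105 times as many for CopiaMBD2 and 93.0 times as many for CopiaMBD3. CopiaMBD1, with the fewest called peaks on native DNA, had the most on amplified DNA.

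Native-DNA peaks were also wider. They covered 1703, 3400 and 3991 kb for CopiaMBD1, CopiaMBD2 and CopiaMBD3, which is 0.981, 1.96 and 2.30% of the effective genome, against 56.6, 21.4 and 26.1 kb on amplified DNA. Median peak width was 196, 200 and 206.5 bp on native DNA and 147, 154 and 144 bp on amplified DNA. Within its own list, median fold enrichment over the HaloTag-only control was 4.32 (interquartile range 3.58 to 5.23), 4.65 (3.78 to 5.80) and 5.28 (4.18 to 6.79) on native DNA, and 3.51 (2.84 to 4.27), 3.53 (3.02 to 4.11) and 3.49 (2.83 to 4.24) on amplified DNA. A −log10 q of at least 10 was reached by 1254, 3623 and 5920 native-DNA peaks and by 19, 4 and 11 amplified-DNA peaks. The ratio of native to amplified peaks depended on the peaks counted, from 7.40 for CopiaMBD1 on sequences spanning at least 100 kb to 906 for CopiaMBD2 at a −log10 q of at least 10. It stayed above 1 for each domain under all 6 alternatives. Paired by domain, a test added after the data were seen, the mean log2 ratio of peak numbers was 5.88 ± 1.3 (SD, n = 3 domains), higher on native DNA in 3 of 3 domains, with an exact two-sided sign-flip permutation p of 0.25, the smallest that 3 pairs can give. Each domain's own ratio has no replicate, and the SD measures the spread between different domains. The 3 pairs share the same HaloTag-only control within each DNA kind, so they are not independent.

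**Figure D1:**
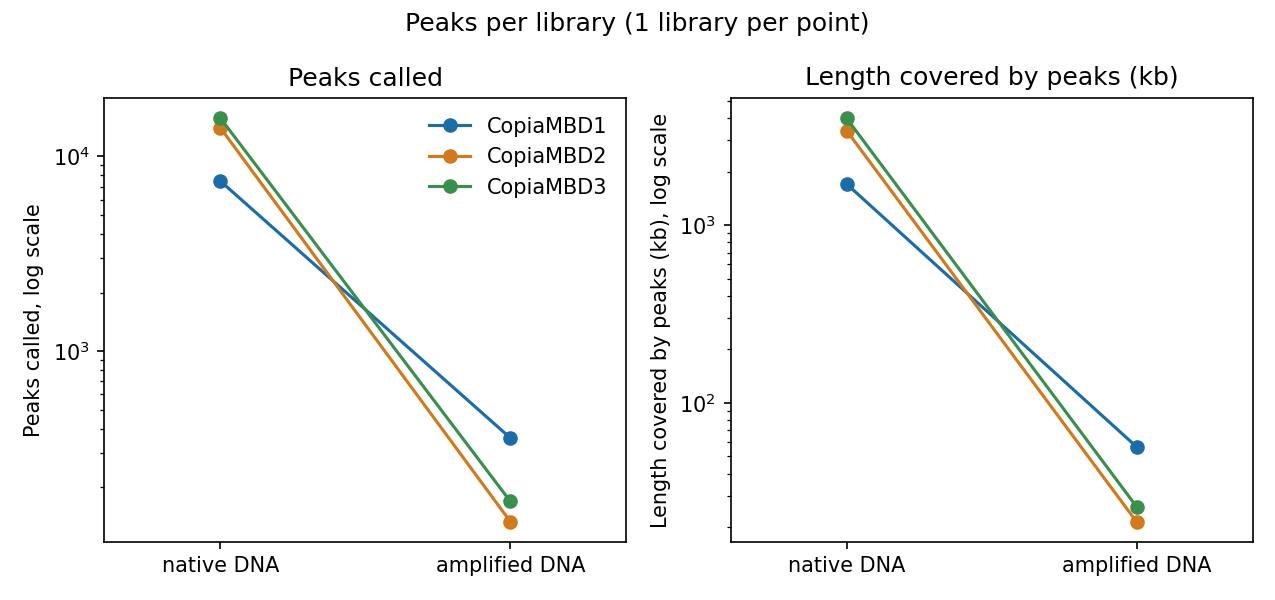
Number of peaks called (left) and length covered by peaks in kb (right) on native and amplified DNA, both on log scales, with 1 library per point and a line joining the points of each domain. The native-DNA points lie between 7461 and 15714 peaks, and the amplified-DNA points between 133 and 358.

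The strongest native-DNA sites were each called for all 3 domains. Fold enrichment peaked for CopiaMBD3 at 34.3 on AFFK01000331 (653 to 979), where CopiaMBD1 reached 9.81 and CopiaMBD2 21.4. The next CopiaMBD3 peaks lay on AFFK01005886 (1219 to 1444, fold 31.6) and AFFK01019298 (2003 to 2342, fold 27.9). The top CopiaMBD2 peaks were on JH430098 (201 to 458, fold 24.3), JH430153 (333 to 631, fold 23.1) and AFFK01002349 (109 to 319, fold 22.5). For CopiaMBD1 they were on JH431324 (954 to 1150, fold 15.7), JH431035 (14533 to 14795, fold 14.4) and AFFK01000617 (412 to 637, fold 14.3). Of these 9 sites, the one on AFFK01005886 also carried amplified-DNA peaks, of fold 3.80 for CopiaMBD2 and 5.27 for CopiaMBD3. Short AFFK contigs, which made up 10.4% of the sequence spanned by peaks, held 39.9, 37.9 and 35.9% of native-DNA peaks and 11.7, 18.8 and 27.8% of amplified-DNA peaks of CopiaMBD1, CopiaMBD2 and CopiaMBD3. Which genes or repeats lie at these positions was not analysed here.

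Scaffold JH432211, chosen for its number of peaks after the values were seen, shows the contrast over a long sequence. Up to position 469037 it held 57 native-DNA peaks of CopiaMBD1, 120 of CopiaMBD2 and 164 of CopiaMBD3. On amplified DNA the same scaffold held 1, 1 and 0 peaks.

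**Figure D2:**
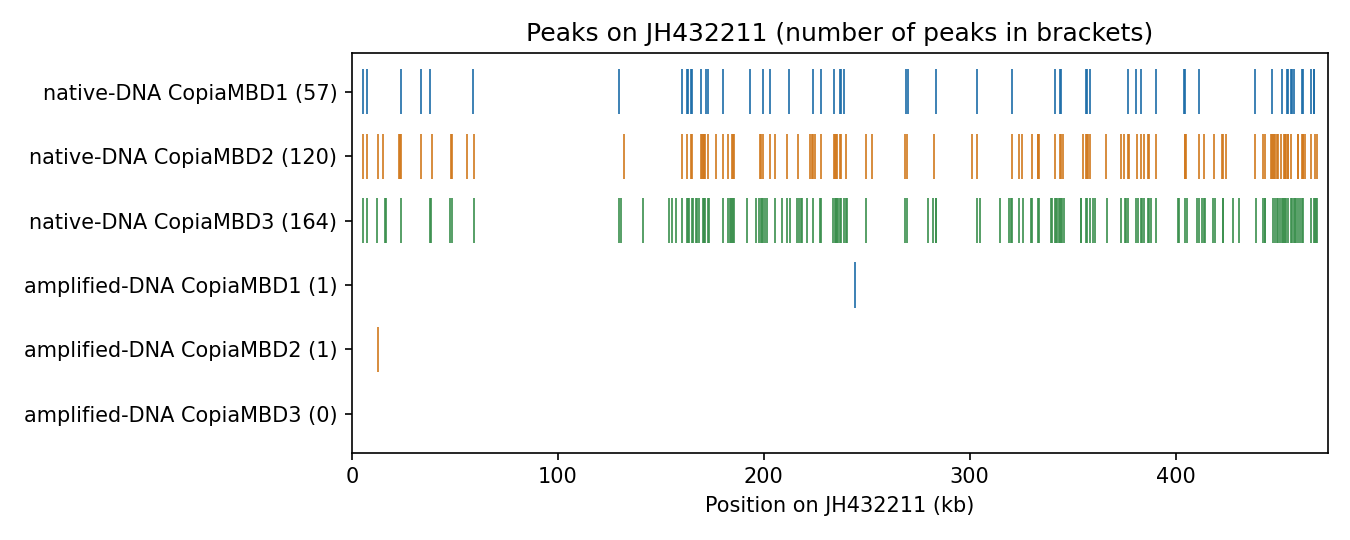
Positions of peaks along scaffold JH432211, in kb, for the 6 peak lists, with 1 tick per peak and the number of peaks in brackets. The native-DNA lists hold 57, 120 and 164 peaks, many at common positions, and the amplified-DNA lists hold 1, 1 and 0.

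On native DNA most CopiaMBD1 sites were also sites of the other domains, while CopiaMBD2 and CopiaMBD3 each had many sites without a CopiaMBD1 peak. Of CopiaMBD1 peaks, 76.4% (exact 95% interval 75.4 to 77.4) overlapped a CopiaMBD2 peak and 75.3% (74.3 to 76.3) a CopiaMBD3 peak, and 64.0% (62.9 to 65.1) overlapped both. CopiaMBD2 and CopiaMBD3 shared 64.7% (63.9 to 65.5) of the CopiaMBD2 peaks and 56.7% (55.9 to 57.4) of the CopiaMBD3 peaks. A CopiaMBD1 peak was present at 40.1% (39.3 to 41) of CopiaMBD2 peaks and at 34.8% (34.0 to 35.5) of CopiaMBD3 peaks. Merging the lists gave 21205 regions, of which 4556 (21.5%) were bound by all 3 domains, 5710 (26.9%) by a pair of them and 10939 (51.6%) by a single domain, namely 915 by CopiaMBD1, 4031 by CopiaMBD2 and 5993 by CopiaMBD3.

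Random placement of the same peaks gave overlaps of 2.37 to 5.21% for the 6 ordered pairs of native lists, and none of 1000 placements reached the observed value (permutation p = 0.001 for each, the smallest they can give). When each sequence's peaks were instead shifted around that sequence, which keeps them on the short contigs, the random overlaps rose to 11.6 to 24.9% and the observed values stayed above them (permutation p = 0.001 for each). The lists share 1 HaloTag-only library, and simulated libraries without binding had at most 0.478% of their chance calls in common. Those simulated lists averaged 251.5 to 444.15 calls, far fewer than the native lists, and their coverage was not fitted to the data. Their common share therefore does not bound what the shared control adds, and part of the excess may come from that control. With stricter lists CopiaMBD1 peaks were found at fewer sites of the other domains, 17.0% of CopiaMBD3 peaks at a −log10 q of at least 10, and 17.4% of CopiaMBD3 and 23.0% of CopiaMBD2 peaks at a fold of at least 5. The asymmetry went with list length: with equal numbers of peaks per list the shares were 51.0 and 49.4% between CopiaMBD1 and CopiaMBD2, 49.3 and 46.9% between CopiaMBD1 and CopiaMBD3, and 59.3 and 58.0% between CopiaMBD2 and CopiaMBD3.

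**Figure D3:**
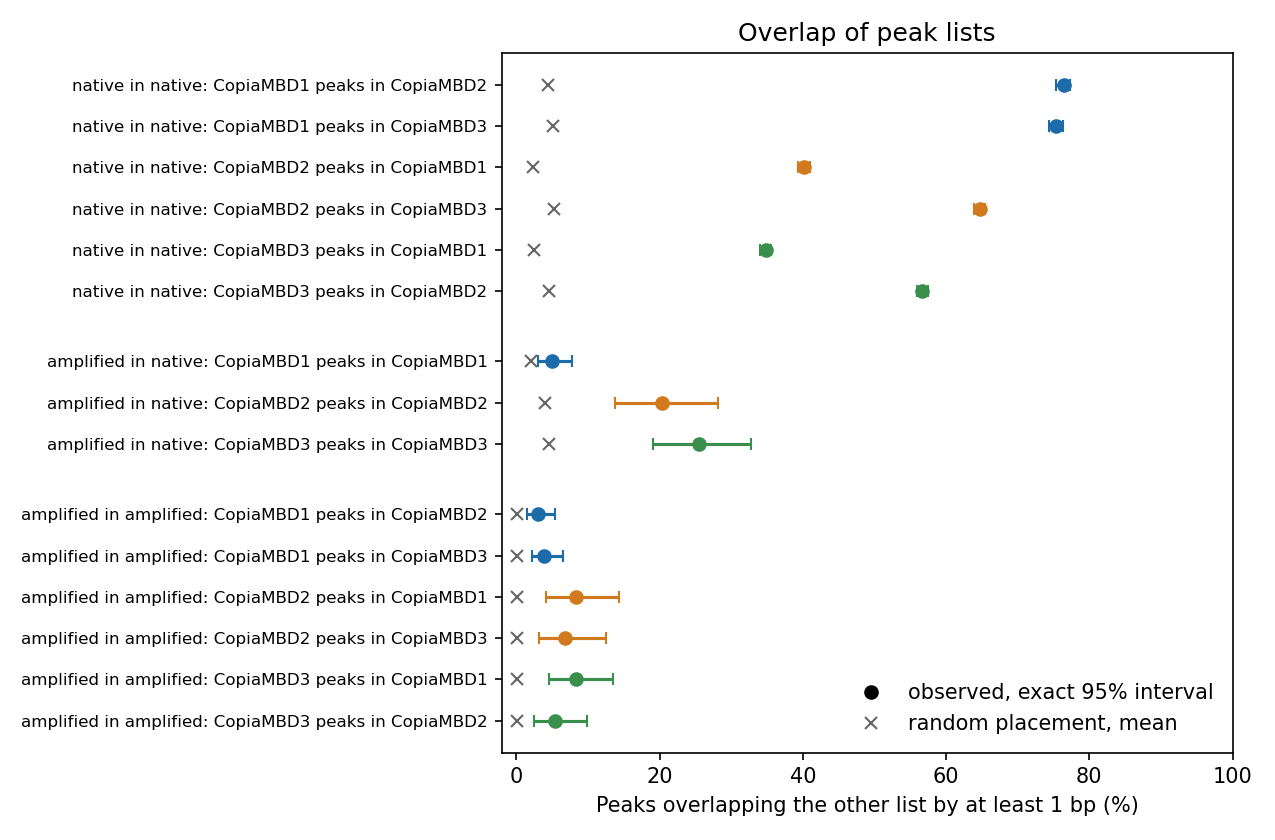
Percentage of peaks of each list that overlap another list by at least 1 bp (points, with exact 95% intervals) and the mean of 1000 random placements (crosses). Native-DNA lists overlap each other by 34.8 to 76.4%, amplified-DNA peaks overlap native-DNA peaks of the same domain by 5.03 to 25.4%, and amplified-DNA lists overlap each other by 3.07 to 8.28%. The lists differ widely in length, so the percentages of the 2 DNA kinds are not comparable.

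At places bound by more than 1 domain, the domains ranked sites alike to a moderate degree. Across overlapping native peaks, which are not independent replicates, Spearman's rho of fold enrichment was 0.37 (95% interval 0.34 to 0.39, 5817 pairs) between CopiaMBD1 and CopiaMBD2, 0.34 (0.31 to 0.36, 5722 pairs) between CopiaMBD1 and CopiaMBD3, and 0.36 (0.34 to 0.38, 9321 pairs) between CopiaMBD2 and CopiaMBD3. Pearson's r on the log2 scale was 0.42, 0.38 and 0.40. Among peaks with a −log10 q of at least 10, rho was 0.66 between CopiaMBD1 and CopiaMBD2, 0.57 between CopiaMBD1 and CopiaMBD3 and 0.45 between CopiaMBD2 and CopiaMBD3. The site on JH431035 (14484 to 14795) had the highest lowest fold of all regions bound by the 3 domains, 14.4, 21.8 and 23.3 for CopiaMBD1, CopiaMBD2 and CopiaMBD3, and was singled out after its values were seen.

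The HaloTag-only library shared by the lists adds covariance to these fold enrichments. The covariance of log2 fold across overlapping peaks was 0.102, 0.0997 and 0.120 for the 3 pairs of domains. In simulated libraries without binding it was 0.0920, 0.0901 and 0.0891 at uniform coverage and 0.124, 0.119 and 0.117 at uneven coverage. The simulated values are over all positions, since almost no chance calls overlapped, so their difference from the observed values does not measure a shared effect. Among the 503, 555 and 912 pairs where the control was at its lowest level in both lists, and so added no variation, the covariance was 0.0879, 0.0836 and 0.0924 and rho was 0.46, 0.42 and 0.47.

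The few amplified-DNA peaks mostly did not overlap a native-DNA peak of the same domain. Part of each list may be chance calls. For CopiaMBD1, CopiaMBD2 and CopiaMBD3, simulated amplified-DNA libraries without binding averaged 90.2, 64.4 and 66.5 calls at uneven coverage. At uniform coverage they averaged 67.1, 41.15 and 47.25. An amplified-DNA peak coincided with a native-DNA peak of the same domain in 18 of 358 cases for CopiaMBD1 (5.03%, 3.01 to 7.83), 27 of 133 for CopiaMBD2 (20.3%, 13.8 to 28.1) and 43 of 169 for CopiaMBD3 (25.4%, 19.1 to 32.7). Random placement gave 2.06, 4.02 and 4.57% (permutation p = 0.002, 0.001 and 0.001), and shifting peaks around their own sequence gave 2.73, 7.91 and 9.95% (permutation p = 0.003, 0.001 and 0.001). Counting native peaks of any domain raised the shares to 12, 24.8 and 31.4%. The shares depended on the length of the native list. With equal numbers of peaks per list they were 0.559, 1.504 and 0.592%, against 0.0927, 0.0376 and 0.0556% at random. Each of these shares rested on very few peaks, and the CopiaMBD3 share was no longer past 0.05 (permutation p = 0.087). The same call was lost for CopiaMBD3 on sequences of at least 100 kb (5.56% against 1.86% at random, permutation p = 0.051), and for CopiaMBD1 where the control level was under 3 times its lowest (2.34% against 1.76%, p = 0.302) and under 4 other settings, although each share stayed above its random value.

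Of the strongest amplified-DNA peaks, the 3 of CopiaMBD1, on JH431516 (62775 to 62910, fold 6.77), JH431584 (70104 to 70241, fold 6.43) and JH430758 (769 to 915, fold 6.22), overlapped no peak of any other list. For CopiaMBD2 the top peak on AFFK01010709 (71 to 216, fold 6.70) was also a native-DNA site, with folds of 8.71, 13.4 and 16.2 for CopiaMBD1, CopiaMBD2 and CopiaMBD3, whereas those on JH431844 (12499 to 12654, fold 6.68) and AFFK01005153 (644 to 824, fold 5.83) were in no other list. The top CopiaMBD3 peak on AFFK01007043 (1071 to 1205, fold 7.20) was a native-DNA site of all 3 domains at folds of 5.75, 6.47 and 6.69, and those on AFFK01017221 (1947 to 2076, fold 6.97) and AFFK01020385 (18372 to 18505, fold 5.65) were in no other list.

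Native sites that kept an amplified-DNA peak were stronger than the rest for CopiaMBD3. Its 42 such peaks had a median native fold of 6.97 (interquartile range 4.61 to 9.02) against 5.28 (4.18 to 6.79) at the other 15672 (permutation test, adjusted p = 0.00015). For CopiaMBD1 the medians were 4.05 at 18 peaks and 4.32 at the other 7443 (permutation test, adjusted p = 0.64), and for CopiaMBD2 they were 4.57 at 27 peaks and 4.65 at the other 13974 (adjusted p = 0.71). Whether the domains differ in this was not tested. The permutation treated peaks as independent, although native peaks lie close together, and did not adjust for peak width. At a −log10 q of at least 10 the CopiaMBD3 comparison rested on 4 peaks and its difference of medians of 0.351 was not past the threshold (permutation p = 0.72).

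On amplified DNA the domains had few peaks in common, in lists of 133 to 358 peaks. Their shares cannot be compared with those of the far longer native lists. Relative to random placement, overlap was 91.7 to 180 times as high on amplified DNA and 12.3 to 17.2 times on native DNA. These ratios depend on list length too: the random share was 2.37 to 5.21% for native lists and 0.0277 to 0.0902% for amplified-DNA lists. They cannot be compared between DNA kinds either. Shifting peaks around their own sequence gave higher random shares, and so smaller ratios, for both kinds. CopiaMBD1 and CopiaMBD2 had 11 amplified-DNA peaks in common, CopiaMBD1 and CopiaMBD3 had 14, and CopiaMBD2 and CopiaMBD3 had 9, which is 3.07 to 8.28% of a list against 0.0277 to 0.0902% under random placement (permutation p = 0.001 for each) and 0.0799 to 0.575% when peaks were shifted around their own sequence (permutation p = 0.001 for each). The 3 lists share 1 HaloTag-only library, and simulated libraries without binding had at most 0.0776% of chance calls in common. Those simulated lists were shorter, with 41.15 to 90.2 calls on average, and their coverage was not fitted to the data. Their common share therefore does not bound what the shared control adds, and part of the excess may come from that control. No pair of domains shared a peak at a −log10 q of at least 10 or at a fold of at least 5, where the lists held 4 to 33 peaks. The shares were 2.26 to 5.26% with equal numbers of peaks per list and 2.78 to 15.3% on sequences spanning at least 100 kb. With the control level under 3 times its lowest, CopiaMBD1 and CopiaMBD2 shared 1.56 and 3.85% of their peaks in place of 3.07 and 8.27%, CopiaMBD2 and CopiaMBD3 shared 2.88 and 2.48% in place of 6.77 and 5.33%, and CopiaMBD1 and CopiaMBD3 shared 3.89 and 8.26% in place of 3.91 and 8.28%. Of 626 merged regions, 592 belonged to a single domain and 34 to a pair of domains. None carried peaks of all 3, which allows a share of up to 0.479% by counting error. Of the 34 regions, 10 had a native-DNA peak and 5 had native-DNA peaks of all 3 domains. Among those 34, chosen after the values were seen, JH431109 (3069 to 3258) had folds of 5.07 for CopiaMBD1 and 4.88 for CopiaMBD2 and no native-DNA peak, and JH430644 (725 to 859) had folds of 6.02 for CopiaMBD1 and 4.70 for CopiaMBD3 with native folds of 7.76, 8.46 and 11.2.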

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

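Both tests of the raised control level were fixed before their own values were computed, and the restriction to low control level was chosen after the results were seen.

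Amplified-DNA peaks lay at higher relative levels of the HaloTag-only control than native-DNA peaks, a signal in control coverage that the comparisons of peaks do not use. The local control level at the summit, relative to the lowest of its list, had a median of 2.174 at CopiaMBD1 peaks, 1.719 at CopiaMBD2 peaks and 1.922 at CopiaMBD3 peaks on amplified DNA. On native DNA the medians were 1.61, 1.49 and 1.36, so each amplified-DNA list stood above each native-DNA list. Positions outside peaks were not measured, and native and amplified DNA have different controls. Tags at repeated positions made up a fraction of 0.03 of the native-DNA control and 0.11 of the amplified-DNA control. A control level of at least 3 times the lowest was found at 28.2, 21.8 and 28.4% of amplified-DNA peaks and at 15.6, 11.8 and 14.5% of native-DNA peaks.

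Neither explanation tested was excluded. Weak enrichment may be callable only where coverage is deep, because a small fold then passes the threshold: native-DNA peaks matched on fold enrichment had median control levels of 2.69, 2.11 and 3.05, at least 1.228 times those of the amplified-DNA peaks. A native peak of low fold can be called only at a high control level, so this comparison could hardly fail and decides nothing. Sequence present in more copies in the DNA than in the assembly is another candidate explanation, under which the native control should be raised at the same sites. Native-DNA peaks with an amplified-DNA peak had median native control levels of 2.69, 2.24 and 2.44 against 1.61, 1.49 and 1.36 at the others, a ratio of at least 1.504 with bootstrap 95% intervals apart in all 3 domains. Both stay open, as does binding of the domains to particular unmethylated sequences, which was not tested because the sequence under the peaks was not used here.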

How the results depend on the processing

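The pairing by domain and the settings without AFFK contigs, with the control level under 3 times its lowest, and with the control at its lowest were chosen after the results were seen. Native-DNA overlaps stayed above random placement in 60 of 60 recomputed values, from 17.0 to 82.2%. Overlaps between amplified-DNA lists stayed past 0.05 in 48 of 60, shares of amplified-DNA peaks on native-DNA peaks in 23 of 30, and comparisons of native fold with and without an amplified-DNA peak kept their side of the threshold in 6 of 7. The ratio of native to amplified peaks and the rho of fold moved beyond their intervals in 16 of 18 and 9 of 12 values.

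In the order CopiaMBD1, CopiaMBD2 and CopiaMBD3, the ratio of native to amplified peaks was 66.0, 906 and 538 at a −log10 q of at least 10, 64.3, 637 and 849 at a fold of at least 5, 18.4, 86.1 and 75.9 with peaks within 500 bp merged, and 7.40, 47.7 and 51.1 on sequences spanning at least 100 kb. Without AFFK contigs it was 14.2 and 80.5 for CopiaMBD1 and CopiaMBD2, and at low control level it was 24.5 and 111 for CopiaMBD1 and CopiaMBD3. Peak numbers behind these ratios were 1254, 3623 and 5920 native against 19, 4 and 11 amplified by q, 2122, 5734 and 8487 against 33, 9 and 10 by fold, and 1532, 3005 and 3681 against 207, 63 and 72 on long sequences, and 4482, 8698 and 10070 native peaks lay outside AFFK contigs.

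The overlap of amplified-DNA with native-DNA peaks stayed above its random value but was no longer past 0.05 for CopiaMBD1 at a −log10 q of at least 10 (5.26% against 0.384% at random, permutation p = 0.071), at a fold of at least 5 (3.03 against 0.582%, p = 0.175), on sequences of at least 100 kb (1.93 against 0.761%, p = 0.062), within 500 bp (7.82 against 6.12%, p = 0.119) and at low control level (2.34 against 1.76%, p = 0.302). The same held for CopiaMBD3 on sequences of at least 100 kb (5.56 against 1.86%, permutation p = 0.051) and with equal numbers of peaks (0.592 against 0.0556%, p = 0.087). The stricter q and fold left 19 and 33 CopiaMBD1 peaks, and for the others the cause was not tested. Amplified-DNA lists overlapped by 0% in all 6 ordered pairs at both stricter thresholds (permutation p = 1), which left 4 to 33 peaks per list. The CopiaMBD3 difference in native fold was 0.351 (permutation p = 0.72) at a −log10 q of at least 10, with 4 peaks. With −log10 q in place of fold, the differences for CopiaMBD1 and CopiaMBD2, which were below 0 for fold, became 1.09 and 0.488, again not past 0.05 (permutation p = 0.21 and 0.66).

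For the pairs CopiaMBD1 and CopiaMBD2, CopiaMBD1 and CopiaMBD3, and CopiaMBD2 and CopiaMBD3, rho was 0.49, 0.46 and 0.45 for −log10 q in place of fold, 0.66, 0.57 and 0.45 among peaks with a −log10 q of at least 10, and 0.46, 0.42 and 0.47 with the control at its lowest in both lists. The cause was not tested. The higher overlap of the 10% of native peaks with the highest fold than of the 10% with the lowest kept its direction in 6 of 6 ordered pairs with the control at its lowest.

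The amplified-DNA lists of 133 to 358 peaks limit every comparison that uses them. At a −log10 q of at least 10, under 3 CopiaMBD1 and CopiaMBD2 peaks had an amplified-DNA peak, so no difference was computed. Alternatives on CpG density, flanking bases, genes and repeats were not run. Paired by domain, the mean log2 ratio of native to amplified peaks was 4.71 to 8.35 under 6 alternatives, each with the exact permutation p of 0.25 that 3 pairs cannot go below.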

Other observations

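The tests of tags used per call, of the spacing of summits and of overlap by fold, at all peaks and at the lowest control level, were chosen after the results they bear on were seen. The prediction for the share of CopiaMBD3 peaks with a CopiaMBD1 peak by fold was written before its own values were computed.

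Native-DNA sites of all 3 domains came in clusters. On the 279 sequences spanning at least 100 kb, 27.0, 38.9 and 42.8% of CopiaMBD1, CopiaMBD2 and CopiaMBD3 summits lay within 1 kb of another summit of the same list, against 7.88, 14.4 and 17.4% when the same number of summits was placed at random on each sequence. On amplified DNA the share was 2.90% of 207 CopiaMBD1 summits against 0.802% at random (permutation p = 0.049), and 0% of 63 CopiaMBD2 and 72 CopiaMBD3 summits against 0.143 and 0.131%, so the lists are too short to say whether clustering differs between DNA kinds. The richest 10% of 10 kb windows held 88.6, 74.7 and 71.0% of the native-DNA peaks. Spreading the same number of peaks at random over the windows of all these sequences gave 63.3, 43.9 and 41.7%. This excess therefore includes differences in peak density between sequences. The window on JH432085 from 90001 to 100000 held 7 CopiaMBD1, 12 CopiaMBD2 and 10 CopiaMBD3 peaks. JH432211 from 450001 to 460000 held 6, 10 and 13, and JH432134 from 110001 to 120000 held 6, 10 and 10. None of these 3 windows, picked for their native-DNA peaks, had an amplified-DNA peak. Each amplified-DNA list was empty in 97.7 to 99.3% of all windows, so this absence carries little weight. By whole scaffold, JH432211, JH431789 and JH431830 held the most native-DNA peaks, 341, 317 and 218 over the 3 lists, which for CopiaMBD3 is 349.7, 203 and 256 per Mb up to the last peak.

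Sites bound more strongly by a domain were more often bound by the others too. Of the 10% of CopiaMBD1 peaks with the highest fold, 93.3% (exact 95% interval 91.3 to 95) overlapped a CopiaMBD2 peak, against 76.0% (72.8 to 79.1) of the 10% with the lowest fold. For CopiaMBD2 peaks with a CopiaMBD1 peak the shares were 77.7% (75.4 to 79.9) and 30.5% (28.1 to 33.0). The rise lay in the higher ranks of fold, and the lowest share of CopiaMBD1 peaks with a CopiaMBD2 peak, 69.7%, was in the middle ranks. The lists share a HaloTag-only library, so the comparison was repeated at peaks with the control at its lowest, where it adds no variation to fold: 93.1% (87.6 to 96.6) against 49.0% (40.6 to 57.4) of CopiaMBD1 peaks had a CopiaMBD2 peak, and 78.1% (72.6 to 82.9) against 11.3% (7.77 to 15.8) of CopiaMBD2 peaks had a CopiaMBD1 peak.

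The share of native-DNA summits within 1 kb of another was at least 2.462 times that of random placement on the same sequences in the 3 lists, above all 1000 placements. At most 26.5% of neighbouring summits came from peaks with edges under 150 bp apart, so splitting at such short gaps was not the main source. A broad region broken at wider gaps would not be counted here, so splitting by the peak caller was not excluded. Peak numbers per 10 kb window correlated between domains across 7662 windows, which are not independent replicates, with rho of 0.63, 0.60 and 0.71 (lowest 0.5954), and no circular shift of a scaffold exceeded 0.22. Clustered sites that the domains have in common were a hypothesis found and tested on the same data. Native-DNA peaks overlap between domains, so counts per window were bound to correlate. The correlations therefore add no separate evidence for shared clusters. Whether the clusters follow methylated gene bodies was not tested.

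The scarcity of amplified-DNA peaks was set against sequencing depth and against the calling threshold. Depth was argued against, because the amplified-DNA calls used at least 1.646 times as many tags as the native-DNA calls. At least 97.44% of native-DNA peaks, placed at their own fold on the amplified-DNA background, would have passed the weakest p called there. That genome-wide background was 2.61 to 2.91 fragments, against 1.65 to 1.87 on native DNA. A higher background raises the count at a given fold, so this comparison could hardly fail. The values show that sites keeping their native fold would have been called, and decide nothing about sites of lower fold. Loss of methylation, the difference that the design names, may account for the scarcity and remains a hypothesis, because other effects of the 11 extra PCR cycles were not tested and each arm is a single library.

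CopiaMBD1 had the fewest native-DNA peaks with at least 1.006 times the tags of the other domains. A CopiaMBD1 peak was present at 73.46% (exact 95% interval 71.2 to 75.6) of the CopiaMBD3 peaks in the highest 10% of fold and at 24.2% of those in the lowest 10%. The share in the highest 10% fell short of the one predicted if CopiaMBD1 calls stop at the weaker sites of the other domains. It still exceeded the share in the lowest 10%, so that explanation was neither met nor excluded.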
